A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

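RNA of Saccharomyces cerevisiae given 2% glucose or 3% pyruvate was measured on 2 arrays of 2 colours, each holding both conditions. Per the labels, total RNA was amplified and labelled with an Agilent linear amplification kit for low RNA input and hybridised following the maker's protocol, and the dyes were swapped between replicate arrays. Strain, culture conditions and time of harvest are not given in the sources used here, and neither are the scanner, extraction software, background correction and normalization.

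The values used were those of the authors' deposited table, a log2 ratio of the channels for 10807 features on each array, with 10 and 6 values missing. The log base was read from the values: on array 1, 935 features lay, to 3 decimals, at log2 of a ratio of whole numbers up to 10, against a median of 136 and at most 232 at other offsets. On array 2, 784 features lay there after subtracting a constant of 0.008 from the values, against a median of 141.5 and at most 401. Such features were read as dim, since ratios of small whole numbers arise from low signals. The table holds no signal over background, so saturated or compressed bright spots could not be looked for. The deposited medians over all features were -0.29 on array 1 and -0.08 on array 2. No source gives the method of scaling or the order of the channels in the ratio. Cy5 over Cy3 is taken as likely, from convention and the labels' channel order.

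The ratio of array 1, with glucose in Cy5, was multiplied by -1 so that both arrays read pyruvate over glucose. The rule set in advance was to turn the columns if they correlated below -0.3 across features and to give only sizes between -0.3 and 0.3, without saying which features count. Over features of named genes the Pearson r was -0.81, over unnamed features 0.86 and over all features 0.157. The last lies where only sizes would have been given. The choice of named-gene features was made after these values were seen, and the dyes in the labels call for the same turn.

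Of the 10807 features, 9202 had 1 gene in the platform's annotation, 0 had several and 1605 had none. Through gene identifiers 9194 features were matched to current names, and 8 kept the older name. Features of a gene were averaged, which gave 5598 genes, 2010 from 1 feature and 3576 from 2. The median gap between features of a gene was 0.03, and in 1 gene, MAL32, it was over 1. Coordinates are not given, because no source used here names a genome build. Members of the lists for which no value was used, such as COB and MEL1, are not analysed here.

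Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 1 coefficient, 1 residual degree of freedom, prior degrees of freedom of 1.67), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A dye term would leave no residual degree of freedom, so the dye effect stays in the residual. Genes at least 2-fold the same way on both arrays were counted without a test. The 27 gene lists were tested with limma's camera (preset correlation of 0.01), adjusted over the lists, and again with an estimated correlation, with fry and against 10000 random lists. Camera with an estimated correlation rests on the 1 residual degree of freedom, so it has very little power with 2 arrays. The values of fry rest on that 1 degree of freedom too. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

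The design, the gene lists, the rule for named genes and the alternatives, except those given as chosen later, were fixed before the data were examined. By that rule the text names the 10 genes with the largest and the 10 with the smallest mean ratio among those past the test and at least 2-fold the same way on both arrays. It also names the 2 members of each list with the largest absolute mean among those of 1 direction on both arrays, and PCK1, FBP1, ICL1, JEN1, HXT1, HXK2, CYC1 and CIT2 whatever their values. The rule gave 68 genes, and any other gene named was chosen after its values were seen. Of these 68, 2 did not pass as members of their lists, RPS2 and SSB1, and 2 that were fixed by name did not pass, HXT1 and HXK2.

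The steps were tested on simulated data with the measured spread for all 5598 genes. With 200 genes changed in the comparison of pyruvate and glucose, limma recovered 0% of those set at 1.5-fold, 0.3% at 2-fold, 67.2% at 4-fold and 90% at 16-fold, over 20 runs, with 5.29% of calls false. With the 2482 called genes set at their measured ratios, 76.1% were recovered and 2.82% of calls were false. The simulated genes were independent, with variances drawn from the prior that limma fitted to these data. False shares near the threshold were therefore built in, and array differences shared by many genes were not simulated.

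The alternatives were centring each array on its median, scaling the arrays, a robust or no moderation, other thresholds, other log bases, single features, medians over features, leaving out genes whose arrays differed, columns left unturned and each array alone. The planned scaling function, run on the ratios as a plain matrix, divides by medians near 0. The version of it made for ratios was added after the counts of the first were seen, and both are reported.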

Results

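Transcript levels of the budding yeast Saccharomyces cerevisiae supplied with 3% pyruvate were compared with those of yeast supplied with 2% glucose, in a comparison of carbon sources. Total RNA of the 2 conditions was hybridised together on each of 2 arrays, with the dyes exchanged between them. Glucose RNA carried Cy5 on array 1 and Cy3 on array 2. Ratios were obtained for 5598 named genes, 3587 of them from several features with a value on both arrays. The number of arrays, 2, limits the precision of every value, and each value below is a mean log2 ratio of pyruvate over glucose ± SD with n = 2. That direction is likely and not stated by any source: it rests on the usual order of Cy5 over Cy3, which is also the labels' channel order. With the opposite order every sign would turn, and the 1519 genes given as higher and 963 given as lower in pyruvate would exchange places. Cy5 and Cy3 would change places too, wherever a ratio is said to lean to a dye. Read that way, 13 of 14 glyoxylate cycle and gluconeogenesis genes and 16 of 16 TCA cycle genes would be higher on glucose. So would ADH2, which glucose represses. These values argue against the opposite order, and the direction of these genes is then no independent result. The labels do not say whether the arrays held separate cultures or the same RNA extracts. The p-values of single genes therefore measure only the spread between these arrays, which may be technical. Those of camera at its preset correlation rest on the spread between genes, taken as nearly independent. They do not measure how well a list's shift would repeat in other cultures. A lean to a dye, below, is the difference of the arrays divided by 2. With 1 array for each dye order, it cannot be told apart from any other difference between the arrays.

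In pyruvate, most measured genes for the use of non-fermentable carbon and for respiration rose, and most for ribosome assembly fell. The lists behind this passed limma's camera, each with an adjusted p = 0.54 to 0.62 with an estimated correlation, and ribosome biogenesis did not pass limma's fry (adjusted p of 0.0692). The values with an estimated correlation, here and below, rest on 1 residual degree of freedom. A list could hardly pass that way, so they decide nothing about the lists. Those of fry rest on 1 residual degree of freedom too, so a list that did not pass fry is not shown to be unchanged. The largest increases were in HSP12, which encodes a small stress protein, at 6.52 ± 0.06 (91.7-fold), and in ADH2, the glucose-repressed alcohol dehydrogenase, at 6.06 ± 0.31 (66.5-fold). JEN1, the permease for lactate and pyruvate, rose by 5.78 ± 0.05 (54.8-fold), and FBP1, the fructose bisphosphatase of gluconeogenesis, by 5.53 ± 0.22. The largest decreases were in TPO2, a polyamine exporter, at -5.27 ± 0.84 (38.6-fold lower), and in MF(ALPHA)2, an alpha-factor pheromone gene, at -5.14 ± 0.01. By limma, 2482 of the 5598 genes (44.3%) changed at an adjusted p under 0.05, 1519 higher and 963 lower in pyruvate. The smallest adjusted p that limma gave was 0.0115, and the smallest change called was 0.40 in size.

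The next largest increases were in TMA10 (5.94 ± 0.08), whose product associates with ribosomes, and in STL1 (5.93 ± 0.28), the glycerol symporter. They were followed by CYB2 (5.57 ± 0.08), the L-lactate dehydrogenase of the mitochondrial intermembrane space, AGX1 (5.46 ± 0.04), an alanine:glyoxylate aminotransferase, IDP2 (5.46 ± 0.09), the cytosolic isocitrate dehydrogenase, and RGI2 (5.43 ± 0.26). Among the decreases, HSP30, a plasma membrane stress protein, fell to -4.80 ± 0.71 and SAG1, the alpha-agglutinin of mating cells, to -3.81 ± 0.70. PHO84, the high-affinity phosphate transporter, stood at -3.71 ± 0.17, FET4, a low-affinity iron transporter, at -3.48 ± 0.84, and PHO3, an acid phosphatase, at -3.28 ± 0.17. TDA6 (-3.25 ± 0.13), SST2 (-2.77 ± 0.10), a regulator that desensitises cells to pheromone, and YOL014W (-2.72 ± 0.01) completed the 10 largest decreases. The limma adjusted p of these 20 genes lay between 0.0115 and 0.0199, and each had the same direction on 2 of 2 arrays, as the rule that chose them required. On both arrays, 713 genes were at least 2-fold higher and 269 at least 2-fold lower in pyruvate, of which 707 and 265 passed limma's test. At 4-fold the counts were 224 and 26, and at 16-fold 32 and 3. Array 1 alone held 1501 genes changed at least 2-fold, against 982 on both arrays. The count of genes past limma was 10 without moderation and 2499 with robust moderation. With the usual moderation it was 757 against a 1.5-fold minimum change and 0 at an adjusted p under 0.01, with 3180 at an unadjusted p under 0.05.

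**Figure D1:**
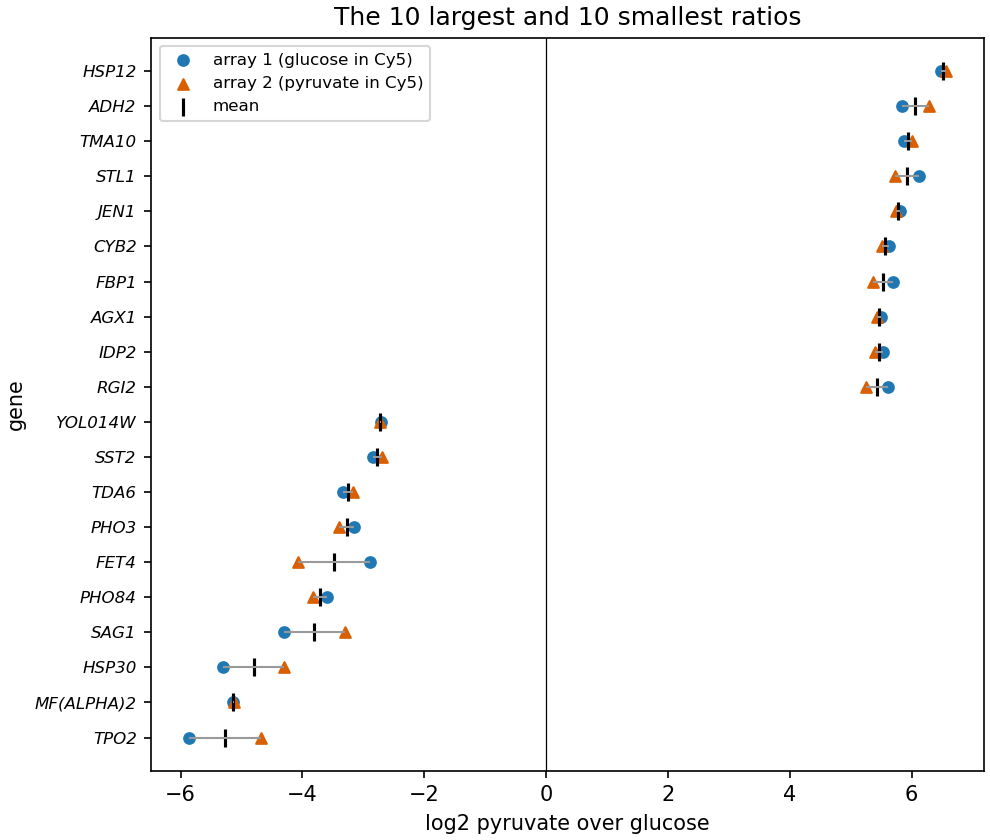
Log2 ratio of pyruvate over glucose for the 10 largest increases and 10 largest decreases, with a circle for array 1, a triangle for array 2 and a bar for the mean. HSP12 stood at 6.52 and TPO2 at -5.27, and the arrays lay farthest apart for TPO2 and FET4.

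Genes of the glyoxylate cycle, gluconeogenesis and the TCA cycle rose. Of 14 measured genes of the glyoxylate cycle and gluconeogenesis, 13 rose, 0 fell and 1 did not pass (13 higher and 0 lower adjusted over the list alone), with a median of 3.72. PCK1, the carboxykinase that forms phosphoenolpyruvate, rose by 4.30 ± 0.05, ICL1, the isocitrate lyase, by 3.80 ± 0.03, and CIT2, the peroxisomal citrate synthase, by 1.58 ± 0.09. limma's camera gave this list an adjusted p of 5.57e-07, against an adjusted p = 0.54 with an estimated correlation. All 16 measured TCA cycle genes rose (16 higher and 0 lower adjusted over the list alone; median 2.83). The succinate dehydrogenase genes SDH1 (4.14 ± 0.12) and SDH4 (4.11 ± 0.05) had the highest ratios of that list. limma's camera adjusted p was 1.83e-07, with an adjusted p = 0.62 with an estimated correlation.

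Of 18 genes for the uptake and use of pyruvate and other monocarboxylates, 12 rose, 2 fell and 4 did not pass, and 13 were higher and 2 lower adjusted over the list alone. Besides JEN1 and CYB2, MPC3, a subunit of the mitochondrial pyruvate carrier, rose by 5.26 ± 0.25, while MPC2, another subunit, was at 0.14 ± 0.01 and did not pass. The genes that fell were MAE1, the mitochondrial malic enzyme (-1.89 ± 0.10), and PYC2, a pyruvate carboxylase (-0.74 ± 0.27), whereas its isoform PYC1 rose by 1.17 ± 0.17. limma's camera adjusted p for the list was 0.00128, with an adjusted p = 0.54 with an estimated correlation.

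Mitochondrial genes rose as sets. In the respiratory chain 21 of 23 genes rose, 0 fell and 2 did not pass (21 and 0 adjusted over the list alone; median 2.78), among them COX12 (3.73 ± 0.03), a subunit of cytochrome c oxidase, and CYC1 (3.43 ± 0.38), the main cytochrome c. COX5B, the oxidase subunit isoform used with little oxygen (-0.25 ± 0.28), and NDE1, an external NADH dehydrogenase (0.39 ± 0.18), did not pass. All 17 genes of the mitochondrial ATP synthase and its regulators rose (17 and 0 adjusted over the list alone; median 2.62), led by INH1, the inhibitor of its ATPase activity (3.77 ± 0.05), and ATP16 (3.01 ± 0.07). All 67 mitochondrial ribosomal protein genes rose (67 and 0 adjusted over the list alone), by less, with a median of 1.29 and extremes of 0.56 and 2.27, the latter in MRPL25; MRPS17 rose by 1.83 ± 0.01. limma's camera adjusted p was 2.73e-08, 7.31e-08 and 2.22e-15 for these lists in that order. With an estimated correlation the adjusted p = 0.57, 0.54 and 0.54.

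Of 24 genes of fatty acid beta-oxidation and the peroxisome, 20 rose, 0 fell and 4 did not pass (22 and 0 adjusted over the list alone; median 2.40). POX1, the acyl-CoA oxidase, rose by 5.23 ± 0.49 and POT1, the thiolase, by 5.19 ± 0.20. limma's camera adjusted p was 7.31e-08, with an adjusted p = 0.54 with an estimated correlation. Of 14 genes for the use of galactose, maltose and sucrose, 8 rose, 0 fell and 6 did not pass (8 and 0 adjusted over the list alone). SUC2, the invertase, rose by 4.84 ± 0.22. MAL12, a maltase, rose by 3.96 ± 0.76, a value left uncertain because probes can bind its near-identical copy MAL32, and features of MAL32 itself differed by over 1 log2 unit. The galactose enzyme genes GAL1 (0.43 ± 0.71), GAL7 (0.21 ± 0.80) and GAL10 (0.28 ± 1.86) did not pass. limma's camera adjusted p was 0.0121 for the list, with an adjusted p = 0.67 with an estimated correlation, and the ratios of this list leaned to Cy3 by a median of -0.48.

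Stress genes and reserve carbohydrate genes rose in the main. Of 30 genes of the environmental stress response, 22 rose, 1 fell and 7 did not pass (23 and 2 adjusted over the list alone; median 1.62). PRX1, the mitochondrial peroxiredoxin, rose by 3.49 ± 0.08, and the gene that fell was HSP42, a small chaperone (-0.83 ± 0.10). The disaggregase gene HSP104 (-0.31 ± 0.07) and the chaperone genes SSA3 (-0.29 ± 0.23) and SSA4 (-0.03 ± 0.12) did not pass. Of 21 trehalose and glycogen genes, 13 rose, 1 fell and 7 did not pass (13 and 1 adjusted over the list alone). GAC1, a phosphatase subunit that promotes glycogen synthesis, rose by 3.70 ± 0.71 and GPH1, the glycogen phosphorylase that breaks glycogen down, by 3.37 ± 0.13. PGM1, a phosphoglucomutase isoform, fell to -1.01 ± 0.04. limma's camera adjusted p was 2.63e-05 for stress and 0.00162 for trehalose and glycogen, each with an adjusted p = 0.54 with an estimated correlation.

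Most genes of ribosome biogenesis fell. Of 65 ribosome biogenesis genes, 59 fell, 0 rose and 6 did not pass (61 lower and 0 higher adjusted over the list alone), with a median of -1.04 (2.06-fold lower). DBP2, an RNA helicase gene, fell to -1.58 ± 0.38 and NOP12, a nucleolar protein gene, to -1.53 ± 0.13. Of 136 cytosolic ribosomal protein genes, 44 fell, 0 rose and 92 did not pass, with a median of -0.60, and 0 were called adjusted over the list alone. The median of this list was -0.87 on array 1 and -0.38 on array 2, and its ratios leaned to Cy5 by a median of 0.22. RPL8B fell to -1.49 ± 0.42, while RPS2, at -1.47 ± 1.19, did not pass as its arrays gave -2.31 and -0.63. Values of paired ribosomal protein genes are uncertain because probes can bind both copies. limma's camera adjusted p was 1.81e-18 for ribosome biogenesis, with an adjusted p = 0.54 with an estimated correlation, and 2.42e-14 for ribosomal proteins, with an adjusted p = 0.67 with an estimated correlation.

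**Figure D2:**
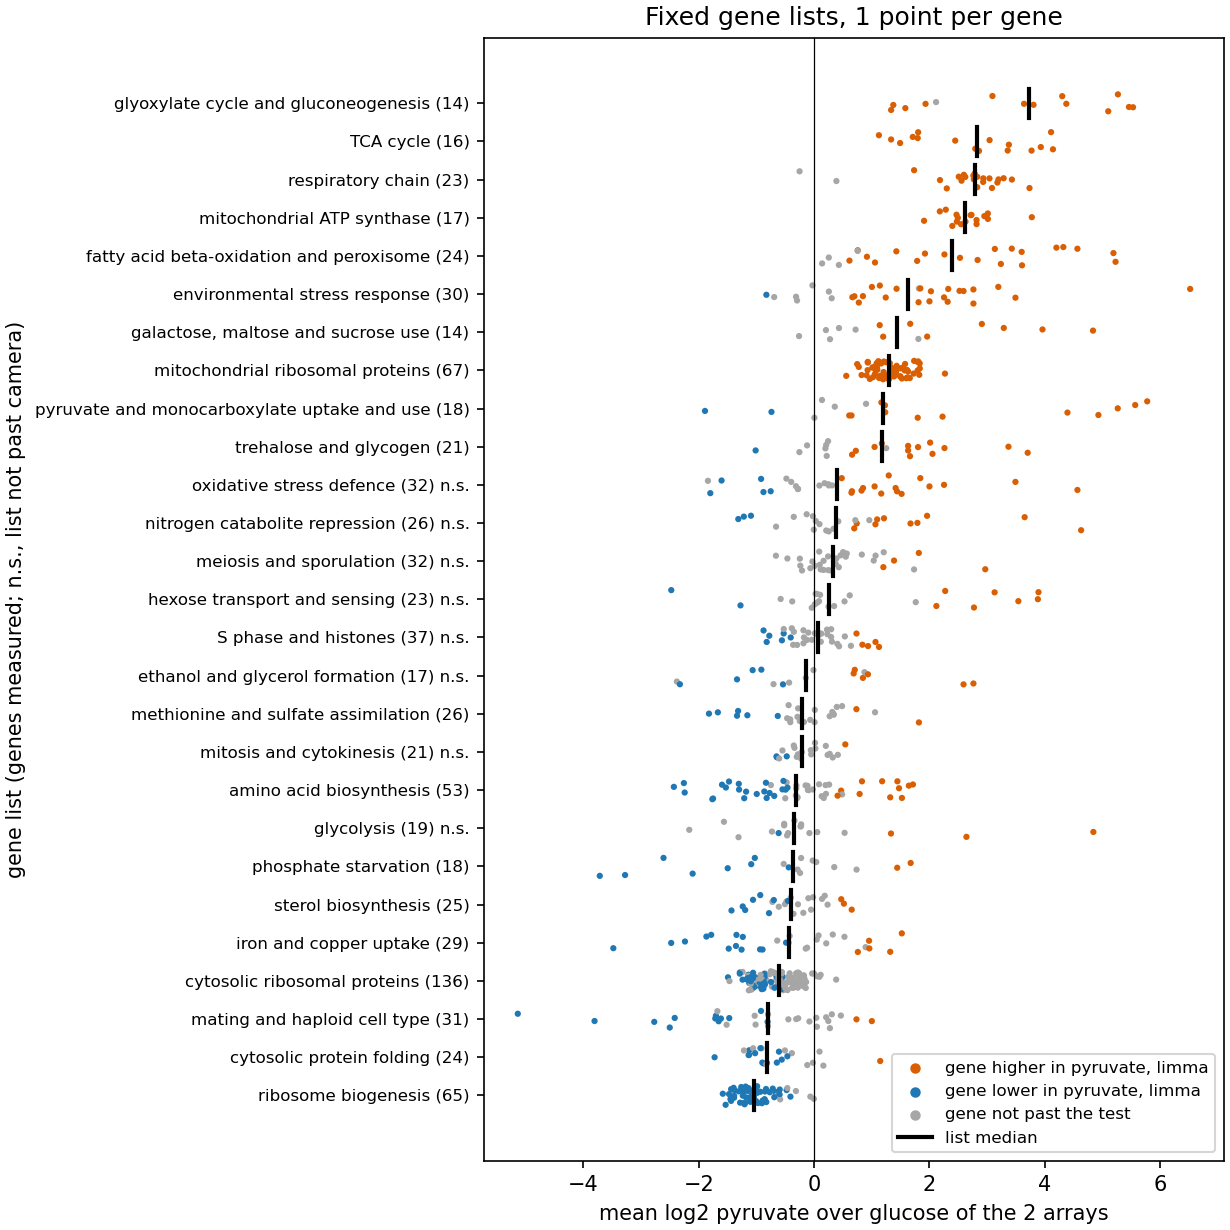
Mean log2 ratio of pyruvate over glucose of each measured gene of the 27 lists, 1 point per gene, coloured by limma's call, with a black bar at the list median and n.s. beside a list not past camera. Medians ran from 3.72 for the glyoxylate cycle and gluconeogenesis to -1.04 for ribosome biogenesis.

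Of 24 cytosolic protein folding genes, 13 fell, 1 rose and 10 did not pass (16 lower and 1 higher adjusted over the list alone). SSA2, a constitutive chaperone gene of the HSP70 family, fell to -1.72 ± 0.36, its relative SSA1 rose by 1.15 ± 0.09, and SSB1, at -1.22 ± 0.67, did not pass. Of 53 amino acid biosynthesis genes, 22 fell, 11 rose and 20 did not pass (24 lower and 11 higher adjusted over the list alone). The lysine pathway genes LYS9 (-2.43 ± 0.28), LYS4 (-2.26 ± 0.15) and LYS20 (-2.24 ± 0.30) fell the most, whereas LEU4 (1.71 ± 0.22) and ARG1 (1.64 ± 0.08), of leucine and arginine synthesis, rose. limma's camera adjusted p was 5.34e-05 for folding, with an adjusted p = 0.63 with an estimated correlation, and 0.00245 for amino acids, with an adjusted p = 0.67 with an estimated correlation. Of 26 genes of methionine and sulfate metabolism, 6 fell, 2 rose and 18 did not pass (6 and 2 adjusted over the list alone). SAM1, an S-adenosylmethionine synthetase, fell to -1.82 ± 0.09, and MET28, a regulator of sulfur genes, rose by 1.82 ± 0.22. The list median, -0.21, was -0.12 on array 1 and -0.33 on array 2. limma's camera adjusted p was 0.0385, with an adjusted p = 0.63 with an estimated correlation.

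Nutrient uptake and sterol lists shifted down with members on both sides. Of 18 phosphate genes, 8 fell, 2 rose and 8 did not pass (9 lower and 2 higher adjusted over the list alone). PHO84 and PHO3 were among those that fell, and the genes that rose were PHO89, a sodium-coupled phosphate transporter (1.67 ± 0.04), and PHM7 (1.44 ± 0.33). Of 29 iron and copper genes, 13 fell, 5 rose and 11 did not pass (13 and 5 adjusted over the list alone). ENB1, a siderophore transporter, fell to -2.48 ± 0.12, and CTR1, the high-affinity copper transporter, rose by 1.52 ± 0.02. The median of the iron and copper list, -0.44, was -0.28 on array 1 and -0.77 on array 2. Of 25 sterol genes, 8 fell, 3 rose and 14 did not pass (11 lower and 3 higher adjusted over the list alone), with ERG7, the lanosterol synthase, at -1.43 ± 0.36 and NCP1, a reductase that serves sterol synthesis, at -1.24 ± 0.13. limma's camera adjusted p was 0.00399, 0.0219 and 0.0039 for these lists in that order. With an estimated correlation the adjusted p = 0.54, 0.62 and 0.73.

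Of 31 mating and haploid cell type genes, 12 fell, 2 rose and 17 did not pass (14 lower and 2 higher adjusted over the list alone), with a median of -0.81. Beyond MF(ALPHA)2, SAG1 and SST2, decreases were measured in AGA1, an agglutinin anchor gene (-2.50 ± 0.37), FUS1, a cell fusion gene (-2.42 ± 0.12), and FAR1, the inhibitor that arrests the cell cycle on pheromone (-1.70 ± 0.05). The other alpha-factor gene, MF(ALPHA)1, was at -0.28 ± 0.09 and did not pass, and STE18 (0.74 ± 0.10) and PRM4 (0.89 and 1.11 on the arrays) rose. limma's camera adjusted p was 8.28e-05, with an adjusted p = 0.54 with an estimated correlation.

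Of 17 hexose transporter genes named HXT, 5 rose, 1 fell and 11 did not pass. HXT3, a low-affinity transporter, fell to -2.48 ± 0.22, while the high-affinity transporter genes HXT6 (3.89 ± 0.24) and HXT7 (3.88 ± 0.18), near-identical copies whose separate values are uncertain, rose together with HXT5 (3.54 ± 0.59). HXT1, at -0.38 ± 0.25, did not pass. In the list of hexose transport and sensing, 7 of 23 genes rose, 2 fell and 14 did not pass (7 and 2 adjusted over the list alone). The median of this list, 0.25, was 1.44 on array 1 and -0.185 on array 2, and its ratios leaned to Cy3 by a median of -0.2. Of 19 glycolytic genes, 3 rose, 1 fell and 15 did not pass (3 and 1 adjusted over the list alone). HXK1, a hexokinase, rose by 4.84 ± 0.17 and GPM2, a phosphoglycerate mutase homologue, by 2.64 ± 0.38, while HXK2, the hexokinase that predominates on glucose, was at 0.53 ± 0.34 and did not pass. GPM3, another such homologue, fell to -0.61. The enolase genes ENO1 (-1.56 ± 0.76) and ENO2 (-2.16 ± 1.36) were at least 2-fold lower on both arrays and did not pass. The median of the glycolytic list was -0.34, with -0.69 on array 1 and -0.10 on array 2, and its ratios leaned to Cy5 by a median of 0.23. Of 17 ethanol and glycerol genes, 6 rose, 5 fell and 6 did not pass (6 and 5 adjusted over the list alone), with ALD3, an aldehyde dehydrogenase, at 2.76 ± 0.04, GPP2, a glycerol phosphatase, at 2.59 ± 0.22 and PDC5, a pyruvate decarboxylase, at -2.33 ± 0.55. limma's camera adjusted p was 0.249, 0.194 and 0.588 for these lists in that order, none past the test, and with an estimated correlation the adjusted p = 0.76 for each.

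Of 32 oxidative stress genes, 16 rose, 5 fell and 11 did not pass (16 and 8 adjusted over the list alone), with CTA1, the peroxisomal catalase, at 4.57 ± 0.29. Of 26 genes under nitrogen catabolite repression, 10 rose, 3 fell and 13 did not pass (10 and 3 adjusted over the list alone), with PUT4, a proline permease, at 4.63 ± 0.05 and GDH2, the glutamate dehydrogenase that releases ammonium, at 3.65 ± 0.06. Of 37 S phase and histone genes, 5 rose, 6 fell and 26 did not pass (4 and 3 adjusted over the list alone), with the near-identical histone genes HHF1 (1.13 ± 0.18) and HHF2 (1.07 ± 0.20) the highest. The median (0.07) and mean (0.05) of this list lay above 0, while camera's direction, relative to other genes, was down. Of 21 mitosis and cytokinesis genes, 1 rose, 3 fell and 17 did not pass (0 and 0 adjusted over the list alone), with AMN1 at -0.65 ± 0.04 and DSE4 at -0.65 ± 0.13. Of 32 meiosis and sporulation genes, 4 rose, 0 fell and 28 did not pass (2 and 0 adjusted over the list alone), with RIM4 at 2.97 ± 0.58 and SPO20 at 1.82 ± 0.47. The ratios of the meiosis list leaned to Cy3 by a median of -0.78. limma's camera adjusted p was 0.229, 0.174, 0.493, 0.103 and 0.357 for these lists in that order, none past the test. With an estimated correlation the adjusted p = 0.63, 0.76, 0.76, 0.63 and 0.88.

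In all, 19 of the 27 lists passed limma's camera at its preset correlation, 10 higher and 9 lower, and 8 did not. With an estimated correlation 0 passed, with a smallest adjusted p = 0.54, and limma's fry, which asks whether a list's genes move on balance 1 way, called 8, all of them higher lists. None of the 9 lower lists passed fry, with an adjusted p of 0.0692 for ribosome biogenesis and 0.218 for ribosomal proteins by limma. The 8 lists that passed had an adjusted p of 0.0446 to 0.0482 by limma's fry, close to the threshold. As fry rests on 1 residual degree of freedom, the lists that did not pass it are not shown to be unchanged.

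Across genes, which are not independent replicates, the turned ratios of the arrays correlated with a Pearson r of 0.81 and a Spearman rho of 0.77, and 83.6% of genes had the same direction on both. The lean, which holds any array difference besides the dye's, exceeded the mean ratio in size in 901 genes (16.1%). By construction, these were the genes whose arrays gave opposite directions. Among the genes with the largest lean to Cy5, chosen after their values were seen, were PDC1, ENO2, ADH1 and TEF2. PDC1, the main pyruvate decarboxylase, was at -3.43 on array 1 and -1.33 on array 2, and ENO2, an enolase, at -3.13 and -1.20. ADH1, the main fermentative alcohol dehydrogenase, was at -1.69 and 0.29, and TEF2, a translation elongation factor gene, at -2.08 and 0.45. PDC1, ENO2 and ADH1 did not pass limma's test. In 93 genes the Cy3 channel was likely at least 2-fold the higher on both arrays, and in 0 genes the Cy5 channel. With the opposite order of the ratio these would be 93 genes for Cy5 and 0 for Cy3. The median turned ratio was 0.18 on array 1 and 0.02 on array 2, with a mean of 0.10. The calls above were tested against 0, and after centring each array on its median limma called 1392 genes higher and 1261 lower.

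**Figure D3:**
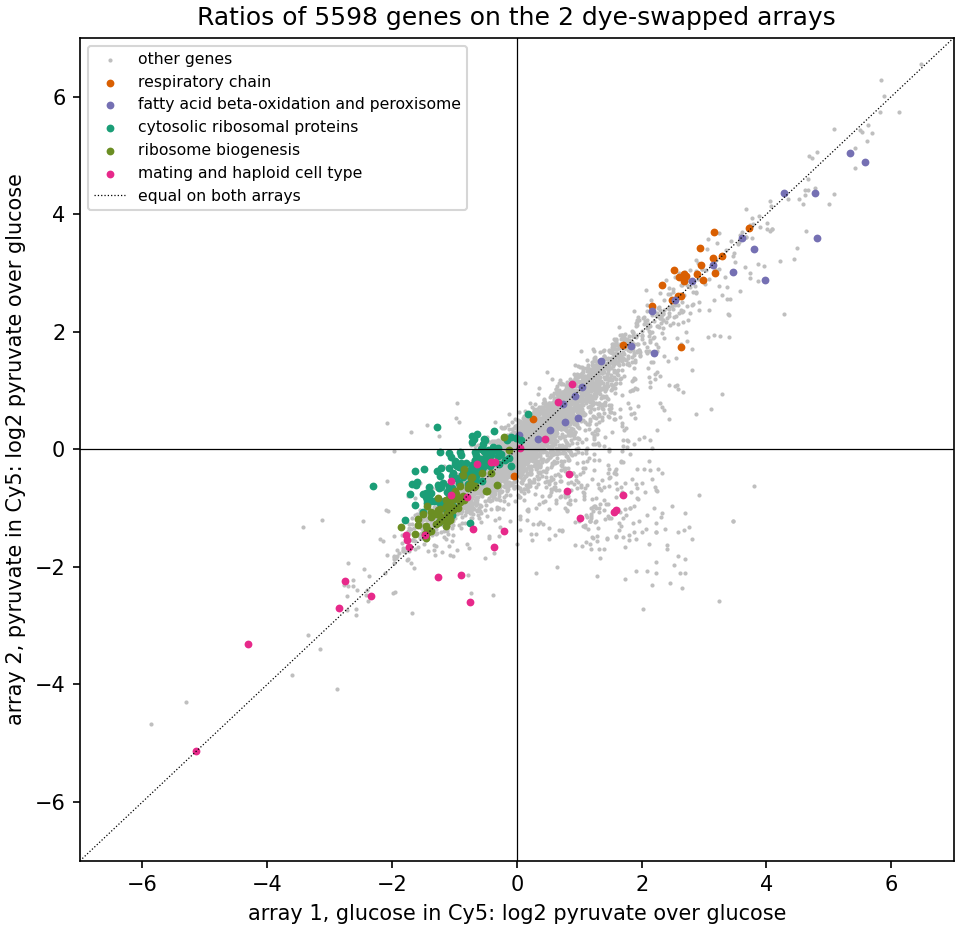
Log2 ratio of pyruvate over glucose on array 1 (x axis) and array 2 (y axis) for 5598 genes, 1 point per gene, with 5 gene lists in colour and a dotted line where the arrays are equal. Most genes lie along that line (Pearson r of 0.81), and 93 genes lie at the lower right, where Cy3 was likely the higher channel on both arrays.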

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

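The tests in this part were chosen after the results were seen, except that of other pheromone-induced genes, which was set before its result was seen, and the settings with arrays centred or taken alone, which were planned.

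Among the 1605 features without a gene name, which no comparison above uses, 60 were at least 2-fold higher and 18 at least 2-fold lower in pyruvate on both arrays. Many more, 654, were at least 2-fold higher in Cy3 on both arrays if the ratio is Cy5 over Cy3, and 2 were in Cy5. Of the 654, 229 lay below -4 on both arrays as deposited, where 0 features of named genes did. The unnamed features correlated between the deposited columns at a Pearson r of 0.86, while those of named genes gave -0.81.

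In 93 genes 1 dye, Cy3 if the ratio is Cy5 over Cy3, was at least 2-fold the higher channel on both arrays, whichever carbon source it carried, and in 0 genes the other dye was. Of the 160 features of these genes, 63.75% lay at ratios of small whole numbers, against 8.91% of other gene features and 0% on a grid moved away from those ratios, so that low signal with an excess of that dye is a candidate explanation for part of the pattern. Such dim features are argued against as the whole source, since 21 of the 93 genes held none, and of the 23 that held dim and other features 18 were still at least 2-fold higher in that dye by the others. A dye bias of single sequences unrelated to brightness is argued against as the whole source too, since 0.439% of genes without dim features were in the pattern (exact 95% binomial interval 0.272% to 0.670%), against 8.87% of genes with them, whose interval did not overlap. For these 39 genes such a bias, and low signal that these ratios do not mark, stay open, and no biological explanation was tested.

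Of the genes at least 2-fold changed on both arrays, 72.6% were higher in pyruvate if the ratio is Cy5 over Cy3 (exact 95% binomial interval 69.7% to 75.4%, with genes not independent), and with the opposite order each share given here as higher would be lower, 713 genes lower against 269 higher. An offset the size of each array's median is argued against as the whole source. After centring each array 66.0% were still higher (62.9% to 69.1%), as were 62.5% on array 2 alone as deposited. Centring takes the median gene as unchanged, so it cannot argue against a larger offset. An offset the size of the medians may account for part, and of all genes past limma 61.2% were higher as deposited and 52.5% after centring. Dim features are argued against as the whole source too, since 72.4% were higher with them left out (69.5% to 75.2%). A total amount of mRNA that differed per cell, if it moved all ratios alike, would be an offset of unknown size and stays open. The carbon source itself and a compression of ratios among bright transcripts stay open and were not tested.

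The mating genes that fell included FUS1, AGA1, SST2 and 3 of 4 alpha-specific genes (list median -2.64), a list formed after these decreases were seen. The alpha-specific gene MF(ALPHA)1 was at -0.275 and did not pass. Fewer alpha cells would lower that gene too, but a single gene does not decide it. Diploid cells in the pyruvate culture are argued against as the whole source: 0 of 5 haploid-specific signalling genes were at least 2-fold lower on both arrays and STE18 rose by 0.74 ± 0.10, although STE4 fell to -0.92 ± 0.19, with GPA1 (-0.80 ± 0.36), FUS3 (-0.31 ± 0.14) and STE5 (0.04 ± 0.01) not past the test. Cells of the other mating type could not be excluded, as the 7 a-specific genes had a median of 0.25, but the arrays' medians had an SD of 1.26, and 5 of their 12 features were dim. The bound was first set by the SD between members, 0.18, which would have argued against such cells, and was changed to the larger SD after these values were seen. Less pheromone signalling in pyruvate may contribute and another effect of the carbon source stays open, yet 10 other pheromone-induced genes had a median at percentile 16.52 of random lists, with CHS1 (-1.26 ± 0.06) and PRM10 (-0.48 ± 0.01) lower and AFR1 (0.55 ± 0.02) higher.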

How the results depend on the processing

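The dim-feature settings, Spearman's rho, the dye-effect settings and the scaling to 1 spread were chosen after results were seen. The count of changed genes, 2482, was within 1.5 times of itself after centring (2653, with 1392 higher and 1261 lower), scaling to 1 spread (2558), robust moderation (2499), medians over features (2481), leaving out genes whose arrays differed (3294) and leaving out dim features (2753). Medians over features could differ from means only in the 12 genes with 3 or 4 features. Leaving out genes whose arrays differed removed genes by the same spread that the test divides by. Neither of these 2 settings is therefore a check of the count. Of the 2482 genes, 2259 were also called after centring, 2431 after scaling to 1 spread and 2431 without dim features. The count was 757 against a 1.5-fold minimum change and 3950 with features fitted singly, which tests more items. Without moderation, on 1 residual degree of freedom, 10 genes passed (1580 at an unadjusted p under 0.05). At limma's adjusted p under 0.01 the count was 0, with 3180 genes at an unadjusted p under 0.05. With the columns not turned limma called 0 genes (45 unadjusted), and with the arrays scaled by their medians, which lie near 0, also 0 (1 unadjusted).

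Genes at least 2-fold the same way numbered 982, with 1928 at 1.5-fold, 250 at 4-fold, 3040 if values were read as log10, 1624 as natural logs, 1585 as single features and 149 with arrays scaled by their medians. Array 2 alone gave 1238 (without replicate 1) and array 1 alone 1501 (without replicate 2), with no test. Centring gave 610 higher and 314 lower. The correlation of the arrays was 0.56 over genes at least 2-fold on 1 array only and 0.77 by Spearman. The lean, which holds the dye effect with any other array difference, exceeded the mean ratio in 1487 single features. Of 27 lists, 19 passed camera as deposited, after centring and without dim features, 8 passed fry, and 0 passed camera with an estimated correlation (0 at an unadjusted p under 0.05). No list turned direction under centring or scaling to 1 spread, although the median of the S phase list went from 0.07 to -0.03 on centring. On each array alone 17 of the 27 list medians, as log2 values, were within 1.5 times of the mean's. Of the 19 lists past camera 16 were, and 3 were not, ribosomal proteins, methionine and iron and copper. On 1 array alone 4 medians changed sign, those of hexose transport, ethanol and glycerol, S phase and meiosis. Of the 68 named genes 64 had log2 values within 1.5 times of their mean on each array alone, and 0 changed sign. The rule that chose them required 1 direction on both arrays, except of the genes fixed by name. RPS2, SSB1, HXT1 and HXK2 were not within 1.5 times, with RPS2 at -2.31 and -0.63. After centring RPS2 and SSB1 newly passed, and the calls of the other named genes held. Except where construction shows it, the cause was not tested. No separate paired analysis was run, since both conditions share each array and each ratio already pairs them. Without signal over background, what low signal limits could be read only from dim features, present in 812 genes.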

Other observations

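The gene families in this part were grouped by shared names and tested after the results above were seen, and the genes named were chosen after their values were seen. The MIC, PET, AIM and ATG families were among those higher in pyruvate. All 6 MIC genes, which encode the complex that shapes the cristae of the inner membrane, rose (median 2.10), with MIC19 at 2.92 ± 0.06 and MIC27 at 2.82 ± 0.06. Of 16 PET genes, named for the respiratory defect of their mutants, 13 rose, 0 fell and 3 did not pass, with PET9, the main ADP/ATP carrier, at 2.11 ± 0.34 and PET100, an assembly factor of cytochrome c oxidase, at 1.92 ± 0.16. Of 29 AIM genes, named for altered inheritance of mitochondria, 19 rose, 1 fell and 9 did not pass. Of 36 ATG genes of autophagy, 20 rose, 1 fell and 15 did not pass, led by ATG39, a receptor for autophagy of the nucleus (4.47 ± 0.20), and ATG36, a receptor for autophagy of peroxisomes (2.54 ± 0.32), with ATG8, the conjugated core protein, at 1.83 ± 0.06. The formate dehydrogenase genes FDH1 (4.71 ± 0.52) and FDH2 (4.59 ± 0.59), near-identical copies with uncertain separate values, also rose. limma's camera adjusted p was 0.0055 for MIC, 0.0062 for PET, 0.000374 for AIM and 0.0062 for ATG, and for each the adjusted p = 0.97 with an estimated correlation.

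The GCD, TRM and RPC families were among those lower. All 7 GCD genes, which encode translation initiation factors and tRNA methyltransferase subunits, fell (median -0.61), and of 15 TRM genes of tRNA modification 10 fell, 1 rose and 4 did not pass, with TRM44 at -1.36 ± 0.08. Of 11 RPC genes, which encode RNA polymerase III subunits, 5 fell, 0 rose and 6 did not pass, with RPC53 at -1.02 ± 0.04. IMD2 (-2.64 ± 0.10) and IMD4 (-2.54 ± 0.33), of guanine nucleotide synthesis, fell as well. limma's camera adjusted p was 0.0062 for GCD, 0.00166 for TRM and 0.014 for RPC, and for each the adjusted p = 0.97 with an estimated correlation. Of 230 families tested, 38 passed camera, and 34 of these also after centring. The PAU family of cell wall mannoproteins (median 0.33, 6 of 24 higher), whose members are so alike that probes can bind several, passed as deposited (limma's camera adjusted p of 0.00743) but had an adjusted p of 0.125 after centring.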
